A study of Mus musculus with 2 samples.

How the data were processed

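RNA was measured in ATDC5, a mouse cell line that forms cartilage nodules when given insulin, transferrin and selenite (ITS). Per the labels, both stable lines carried a doxycycline-inducible transgene, GFP in the control line and A-CEBP in the other, and received 2 µg/mL doxycycline for 2 days and ITS for 3 weeks. A-CEBP is a dominant-negative protein that pairs with C/EBP transcription factors and keeps them from binding DNA. Each group held 1 sample and 1 array, so no spread between cultures could be estimated, and no p-value or standard error between the groups was computed.

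Cy3-labelled cRNA was made from 0.1 µg total RNA and hybridised to 1-colour Agilent mouse arrays, per the labels. The deposited scanner files hold spot intensity on a linear scale, which per the file headers was background-subtracted and detrended within each array by Agilent Feature Extraction, version 10.10.1.1 in the submitters' processing notes. No scaling between arrays had been applied to these values. Both arrays were on 1 slide and came from 1 scan, per the file headers. The authors' deposited table of the series also holds intensity: each of its columns was the processed signal of that array multiplied by 1 constant, 1.24 for GFP and 1.15 for A-CEBP, over all 59305 non-control spots, with column medians of 70.9 and 67.4. It is on a linear scale and is not centred, and how the constants were chosen is not given in the sources used here.

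For the main values, log2 of the processed signal was taken and the 75th percentile of each array subtracted, so that 0 marks that percentile. Control spots were left out, as were 293 spots marked as non-uniform or population outliers on either array. Replicate spots of a probe were averaged. A probe counted as well above background on an array when over 50% of its spots carried that mark. A gene was represented by the probe with the highest mean signal among those well above background on both arrays. Genes well above background on 1 array only were given a lower bound on the fold: the bright value against the higher of the dim probe's own value and the lowest value of any probe well above background on the dim array. Such a bound takes no account of measurement error in the dim value. Differences are A-CEBP minus GFP throughout, and the size rule was 2-fold.

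The scanner files name probes by transcript accession. Of 55671 probes, 27229 (48.9%) matched 1 gene of a RefSeq table of the mouse assembly GRCm38.p6, used for names and gene order only, which gave 20657 genes with a probe. The other 28442 probes stayed unnamed and entered no gene count. Probes of close relatives, such as Saa1, Saa2 and Saa3, Lyz1 and Lyz2, or members of the Oas, Gbp and Ifit families, can share signal, and single values within these families are uncertain. No probe was named for either transgene, and where the Cebpa probe lies relative to the A-CEBP construct was not determined, so expression of the transgenes was not checked.

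The 23 gene lists, 4 of them primary, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the 12 genes with the largest difference in each direction among genes whose probes all differed in the same direction. It also took the 4 largest lower bounds in each direction, up to 8 members at least 2-fold apart from each primary list, and every C/EBP family member seen. From each of the other lists it took up to 4 members with the largest differences. A fixed set of chondrocyte genes and 5 reference genes were named whatever their value. Genes named outside this rule are said to be so. For each list, the median difference was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. This percentile describes these arrays and is not a test of the groups. Some lists share members, so their percentiles are not separate results. Runx2, Alpl and Dmp1, for example, are in both the hypertrophic chondrocyte and the osteoblast lists, and Ihh is in both the hypertrophic and the hedgehog lists.

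Measurement error was taken from replicate spots of a probe, from different probes of a gene, and from the error model of the scanner software. Precision is limited by the number of arrays, and these errors cover the measurement only, not differences between cultures. The procedure was tested on simulated data, in which 200 genes of the GFP array were changed by known folds and replicate-spot noise was added, over 13860 genes. All 40 genes changed 3-fold, all 40 changed 4-fold and all 40 changed 8-fold passed the 2-fold rule, as did 24 of 40 changed exactly 2-fold, 0 of 40 changed 1.5-fold and 0 of 13660 unchanged genes. The added noise, with an SD of 0.06 to 0.18, lay far below the log2 threshold of 1, so the absence of calls among unchanged genes followed from the design. It gives no rate of false calls among the measured differences, whose SD over genes was 0.42. In a first run of 200 random lists of unselected simulated genes, 9.5% fell outside the central 95% of the percentiles. A further run of 2000, added after that share was seen, gave 4.85%. These lists were drawn from the same simulated genes as the lists they were ranked against, so the shares check the calculation only. Lists of genes that vary together were not simulated.

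Alternatives covered median scaling, quantile normalization, cyclic loess, no scaling, normexp background (offset 50) with and without quantile normalization, other detection filters, the mean of a gene's probes, outlier spots kept, the authors' deposited values, other size rules and unmatched random lists. The normexp alternative had been planned on mean spot signals and was run on median signals, which the files hold. Scaling on the E1A spike-in spots was added after seeing the data. Work was done in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and in R 4.3.3 with limma 3.58.1.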

Results

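A-CEBP was compared with GFP in ATDC5 chondrogenic cells after 3 weeks of ITS differentiation, to ask how blocking C/EBP factors altered gene expression in chondrocytes. Each group was represented by 1 array. Of 59305 non-control spots, 32369 (54.6%) were well above background in the GFP sample and 34418 (58.0%) in the A-CEBP sample, and no spot was saturated. The 75th percentile of the processed signal was 872 and 906 intensity units. Across 13860 genes well above background on both arrays, the log2 signals correlated with Pearson's r = 0.989, where genes are not independent replicates, and the median log2 difference was 0.04. There was no replicate check of any difference. The SD of the log2 difference over replicate spots of a probe was 0.12 (root mean square, 266 probes), falling from 0.18 in the dimmest group of probes to 0.06 in the brightest, and that between probes of a gene was 0.19 (3601 genes). The scanner's error model gave a median error of 0.20.

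Genes of the acute phase and of inflammation made up most of the largest differences and were lower in the A-CEBP sample. Lcn2, which encodes an iron-scavenging acute phase protein, was 125-fold lower (log2 difference -6.96), and the neutrophil chemokine Cxcl1 was 83.8-fold lower. The monocyte chemokines Ccl7 and Ccl2 were 56.7-fold and 53.1-fold lower, and the acute phase genes Saa1 and Hp 47.1-fold and 30.8-fold lower. C3, the central complement component, was 31.0-fold lower (log2 difference -4.96, against -3.38 for its other probe) and Chil1 29.2-fold lower. Saa3 was among the brighter genes of the GFP sample, at 6.08, and was not well above background in the A-CEBP sample. Its bound of 2069-fold is the ratio of its 2 readings, since the dim one, -4.935, lay above the lowest value of -5.1853 used for bounds. Its size is uncertain, because the dim reading was not told apart from background. The corresponding bounds were at least 185-fold for Cxcl5, at least 95.1-fold for Wfdc17 and at least 82.7-fold for Saa2. In the fixed list of acute phase and inflammatory genes linked to C/EBP factors, 19 of 32 members measured on both arrays were at least 2-fold lower, none was at least 2-fold higher, and 9 further members were well above background in the GFP sample only. The list's median was -1.28, below all 10000 random lists.

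Interferon-response genes were lower as well. Of 33 members measured on both arrays, 25 were at least 2-fold lower and none was higher at any size, with a median of -1.50, again below all 10000 random lists. Cxcl10, a chemokine induced by interferon, was 38.5-fold lower, the antiviral genes Oas2 and Rsad2 20.1-fold and 11.3-fold lower, and Oas1a 9.27-fold lower. Oas3, seen in the GFP sample only, was at least 8.25-fold lower. Gbp5 and the inflammatory caspase gene Casp4, named among the largest differences of all genes, were 22.6-fold and 35.6-fold lower. Gbp5, Oas2 and Casp4 were dim in the A-CEBP sample, at -4.61, -4.22 and -4.17, so the sizes of their differences are less certain. The macrophage and leukocyte list moved less: its median was -0.14 over 11 members (percentile 3.06), or 0.08 with spike-in scaling, with Ctsk 2.04-fold lower, Cd14 1.79-fold lower, Lyz2 1.77-fold lower and Lyz1 1.42-fold lower. Of its 23 members with a probe, 12 were not well above background in the GFP sample.

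The C/EBP family itself differed by member. Cebpd was 3.70-fold lower (-1.89) and Cebpb 1.92-fold lower (-0.94) in the A-CEBP sample, while Cebpa differed by 0.23, Cebpg by -0.13 (0.09 with spike-in scaling), Cebpz by -0.27 and the C/EBP-related Ddit3 by -0.41. Of 14 members of the list of C/EBP factors and partners, 1 was at least 2-fold lower and none higher. Its median was -0.16 (percentile 0.05), and turned to 0.07 with spike-in scaling.

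Cartilage matrix genes were higher in the A-CEBP sample. Of 31 members measured on both arrays, 7 were at least 2-fold higher and none was lower by that size, with a median of 0.59, above all 10000 random lists. These 7 were the link protein gene Hapln1 (1.42), Snorc (1.37), Acan, which encodes aggrecan (1.30), the receptor gene Fgfr3 (1.16), Papss2 (1.03), Fmod (1.02) and Cnmd (1.02), all as log2 differences. The other probe of Fgfr3 differed by 0.73, under the 2-fold rule. Papss2, Fmod and Cnmd lay just past the rule, and fell under it with the authors' deposited values. Col2a1, the main collagen of cartilage, and its regulator Sox9 stayed within 2-fold, at 0.43 and 0.61. Several other lists also lay at percentile 100, among them muscle (median 0.56) and osteoblast (0.32), so that rank was not particular to cartilage. Among hypertrophic and mineralising chondrocyte genes, 4 of 33 were at least 2-fold higher and 1 was lower, with a median of 0.53, above all random lists. The hedgehog ligand gene Ihh was 2.94-fold higher, Smpd3 2.81-fold, Dmp1 2.48-fold and Clec3a 2.17-fold higher, whereas the collagenase gene Mmp13 was 2.11-fold lower. Col10a1, the collagen of hypertrophic cartilage, was 1.96-fold higher, and Alpl, Cdkn1c, Vegfa and Runx2 differed by 0.83, 0.82, 0.53 and 0.37, with other probes of Vegfa and Runx2 at 0.28 and 0.05.

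Genes of glycolysis and of the response to hypoxia were higher in the A-CEBP sample, with 10 of 34 at least 2-fold higher and none lower by that size. Their median was 0.70, above all random lists. On the log2 scale Ankrd37 differed by 2.04, Egln3, which encodes a HIF prolyl hydroxylase, by 2.00, Adm by 1.38 and Bnip3 by 1.33. Mxi1, seen in the A-CEBP sample only, was at least 2.51-fold higher.

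**Figure D1:**
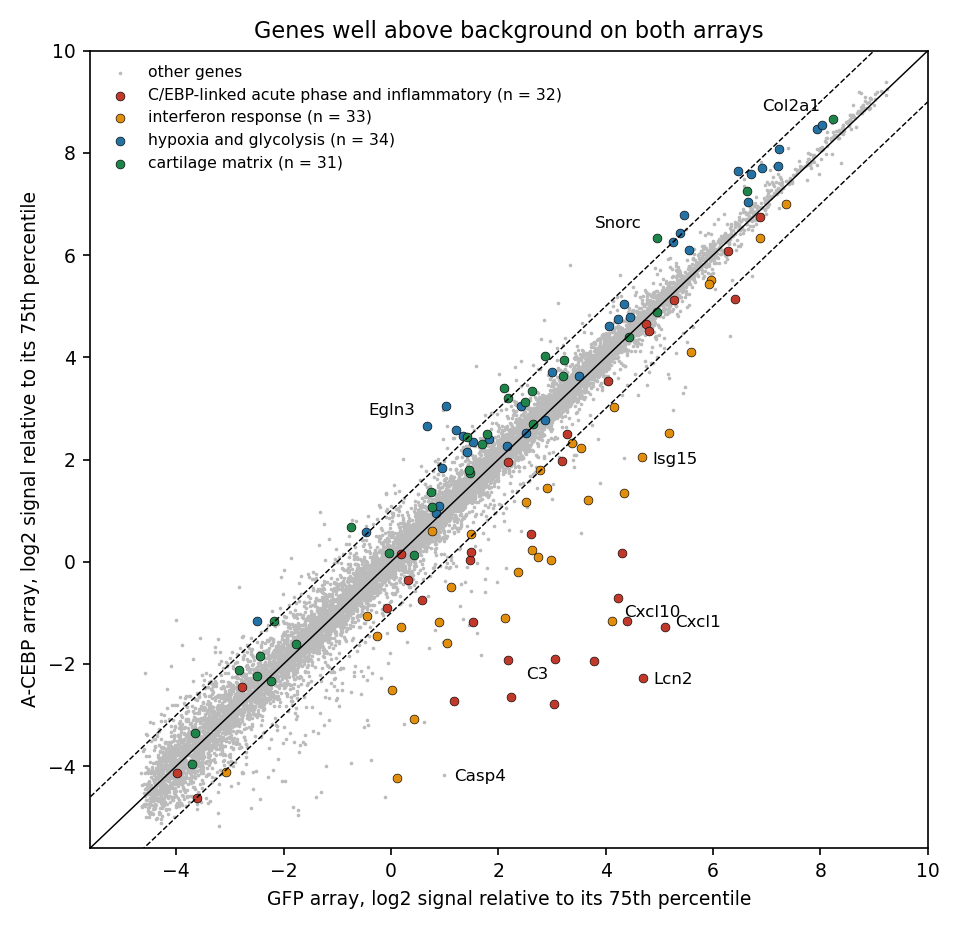
Log2 signal of each of 13860 genes in the GFP sample (x axis) and the A-CEBP sample (y axis), each relative to the 75th percentile of its array, with 4 gene lists in colour. The solid line marks equal signal and the dashed lines 2-fold differences; 19 of 32 inflammatory and 25 of 33 interferon-response genes lie below the lower dashed line, and 10 of 34 hypoxia and 7 of 31 cartilage genes above the upper one.

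Across the array, 410 genes (2.96%) were at least 2-fold apart, 173 higher and 237 lower in the A-CEBP sample, so that 42.2% of them were higher. The count depended on the processing, and fell to 272 with normexp background (98 higher and 174 lower). With scaling on spike-in spots, chosen after seeing the data, 351 were higher and 172 lower (67.1% higher), since that scaling moved the median of all genes from 0.04 to 0.27. At 4-fold or more, 11 genes were higher and 70 lower, and at 8-fold or more none was higher and 28 were lower. A further 171 genes were well above background in the GFP sample only and 674 in the A-CEBP sample only, but the bound reached 2-fold for 97 and 63 of them. The lowest signal of a spot well above background was 24.80 units on the A-CEBP array against 32.93 on the GFP array, so fainter spots could pass on the former. The largest log2 differences upward were those of the oxygen-binding protein gene Mb (2.86, or 7.26-fold), Tmem119 (2.48), Prrt2 (2.42), Gpr35 (2.32), the chloride channel gene Ano1 (2.29), Sapcd1 (2.26) and Ndufa4l2 (2.25). Kcna6, Prdm15, Ankrd37, Egln3 and Rflna followed at 2.07, 2.06, 2.04, 2.00 and 2.00. The other probe of Gpr35 differed by 1.34, and that of Egln3 by 1.76. Several of these genes were dim in the GFP sample, where the lowest probe well above background was at -4.72. Prrt2 was at -4.59, Prdm15 at -4.10, Mb at -4.01, Sapcd1 at -3.89 and Kcna6 at -3.56, so the sizes of their differences are less certain. Tmem119 and Ndufa4l2 were brighter there, at 3.33 and 1.58. Among genes seen in the A-CEBP sample only, Olfr1311 was at least 9.85-fold higher, Ucn2 at least 8.80-fold, Spink10 at least 7.47-fold and Magee2 at least 6.27-fold.

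Signalling lists of the growth plate were mostly higher with small differences. In the hedgehog and PTHrP list, 2 of 12 members were at least 2-fold higher and 1 lower (median 0.45, or 0.20 without the detection filter, percentile 100), with the hedgehog target Gli1 2.52-fold higher, Gli2 1.70-fold higher and Gas1 2.11-fold lower. The 3 probes of Gas1 ranged from -1.32 to -0.46, so that its place past the 2-fold rule rested on the probe taken. In the Wnt list, 3 of 41 were at least 2-fold higher (median 0.36, percentile 100), namely Lgr5 at 2.42-fold and the secreted inhibitors Frzb and Sfrp4 at 2.36-fold and 2.00-fold, while Wnt4 was 1.99-fold lower. With the authors' deposited values Sfrp4 fell under the 2-fold rule and Wnt4 passed it. In the FGF and IGF list, 1 of 32 was higher and 1 lower (median 0.36, percentile 100), and the latter, Igfbp3, was 3.83-fold lower. Of 41 BMP and TGF-beta genes, 1 was higher and 2 were lower (median 0.19, percentile 100): Id2 was 2.02-fold higher, Inhbb 2.22-fold lower and the BMP antagonist Grem1 2.12-fold lower.

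Lists of other mesenchymal lineages gave mixed members. The osteoblast list had 1 of 27 genes at least 2-fold higher, Dmp1, and 1 lower, Pdpn (2.68-fold), with a median of 0.32 (percentile 100), and Tnfsf11, seen in the A-CEBP sample only, was at least 2.01-fold higher. Myf6, Ttk, Cdh1, Tnfsf11, Oas3 and Mxi1 were named after their values were seen. The list of fibroblast, perichondrium and tendon genes had 1 of 39 higher, Cd34 (2.69-fold), and 3 lower, Pi16 (3.40-fold), Fbln1 (2.39-fold) and Fap (2.14-fold), with a median of 0.22 (percentile 100). In the adipocyte list, which holds targets of C/EBP factors, 1 of 28 was at least 2-fold lower, the fatty acid carrier gene Fabp4 (3.77-fold), and the median was 0.03 (percentile 44.6). Of 13 muscle genes 3 were at least 2-fold higher, Mb, Tnni2 (2.58-fold) and Tnni1 (2.48-fold), while Myf6, seen in the GFP sample only, was at least 2.92-fold lower; their median of 0.56 (percentile 100) turned to -0.09 without the detection filter. The endothelial list (9 members, none 2-fold apart) had a median of 0.19 (percentile 93.2). The epithelial and neural list had 1 of 16 lower, Krt8 (2.04-fold), with a median of 0.27 (percentile 99.8), and Cdh1, seen in the A-CEBP sample only, was at least 2.59-fold higher. Krt8 was dim in the GFP and A-CEBP samples, at -3.635 and -4.663, so its place past the 2-fold rule is uncertain.

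Among 38 matrix proteases and inhibitors, 5 were at least 2-fold lower and 1 higher. Mmp3, encoding stromelysin, was 14.9-fold lower, Adamts7 3.99-fold lower and Mmp13 2.11-fold lower, and Adamts15 was 3.20-fold higher. Adamts15 was dim in the GFP sample, at -4.18, so the size of its difference is less certain. The median of -0.05 (percentile 0.68) turned positive without scaling and with spike-in scaling. No gene of 41 measured on both arrays for the S and G2/M phases of the cell cycle was 2-fold apart, and Ttk, seen in the GFP sample only, was at least 2.91-fold lower; the list's median of -0.06 (percentile 0.43) turned to 0.16 with spike-in scaling, and Cdt1, at -0.51, differed most among the 41. Of 22 cell cycle inhibitors and senescence genes 1 was at least 2-fold lower, Gas1, with 1 probe at -0.46, and the median was 0.08 (percentile 77.2), with Cdkn1a 1.80-fold higher and Gadd45a 1.86-fold lower. None of 39 genes of ATF4 signalling and the unfolded protein response was 2-fold apart (median 0.09, percentile 80.0). In the stress and immediate early list, 2 of 30 were at least 2-fold lower, Mt2 (2.20-fold) and Junb (2.05-fold), and the median of -0.05 (percentile 0.36) turned positive without scaling and with spike-in scaling.

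None of 20 reference genes was 2-fold apart (median 0.10, percentile 79.3). Actb differed by 0.12, Hprt by 0.17, Ppia by 0.14 and Tbp by 0.09. Gapdh and Pgk1, which also encode glycolytic enzymes, differed by 0.42 and 0.85, and the 7 probes of Gapdh reached up to 0.85.

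**Figure D2:**
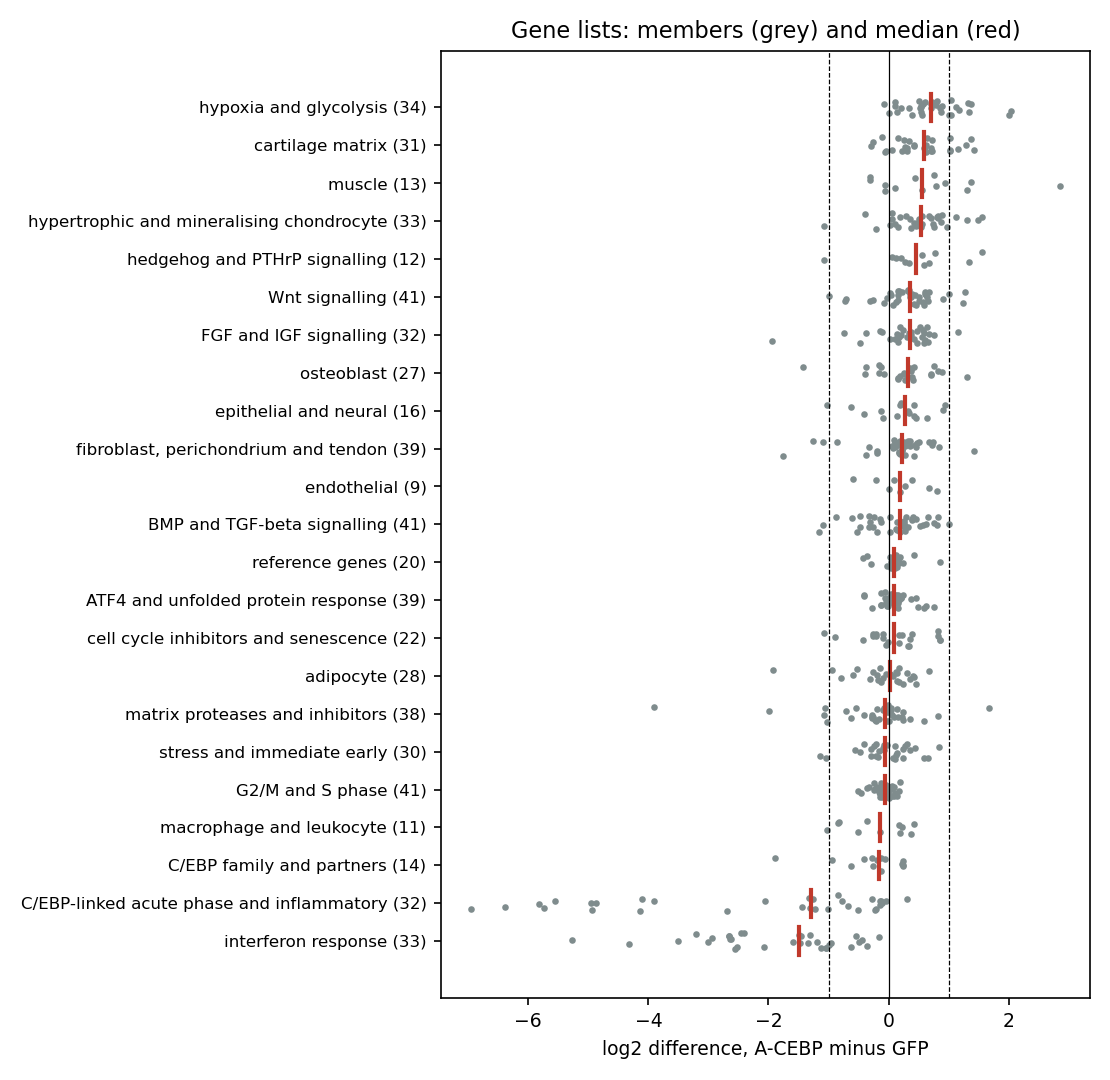
Log2 difference (A-CEBP minus GFP, x axis) of each gene measured on both arrays in the 23 fixed lists, with the number of genes in parentheses; grey points are genes and red bars list medians. Dashed lines mark 2-fold differences, and list medians run from -1.50 for the interferon response to 0.70 for hypoxia and glycolysis.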

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

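The leukocyte tests, and the sets of NF-kB, HIF and respiratory chain genes, were chosen after the main differences had been seen, and the tests of neighbouring spots and of members with several spots were added once the test of other probes had been run. Probes that matched no gene name were not part of the comparison. They passed the 2-fold rule less often than named genes, of which 237 of 13860 were lower and 173 higher. Of 11138 unnamed probes well above background on both arrays, 165 were at least 2-fold lower and 57 at least 2-fold higher in the A-CEBP sample. Among 5598 of these that the array design places in a chromosome interval (mouse build mm9), 101 were lower and 32 higher by that size. The largest was the single probe of the interval on chromosome 9 from 75316023 to 75344401, 36.6-fold lower, and the largest in the other direction was the single probe on chromosome 8 from 108153471 to 108159672, 9.82-fold higher. Of 111 such probes 2-fold apart whose interval had another measured probe, 80 lay in intervals with every probe in the same direction and 31 had another probe in the opposite direction. The 2 intervals named were picked after their values were seen, and what the intervals transcribe was not determined.

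Inflammatory and interferon-response genes were lower in the A-CEBP sample. A scaling or background artefact is argued against, since the least negative median of the 2 lists over 8 such alternatives was -1.06, and so is a local artefact of the slide, since 1028 spots within 2 rows and columns of the members' spots had a median difference of 0.0276 (quartiles -0.14 and 0.18). Single faulty spots are argued against for 5 of the 44 lower members, whose 6 other probes were all (100%) at least 1.5-fold lower. Every spot of the 11 members with several spots was so too (100%, exact 95% interval from 71.5%). That count takes in the same other probes and the spots by which members were chosen, so it adds little separate support. The remaining 33 members had 1 spot only. RNA of leukocytes in the GFP culture as the whole cause is argued against, by a rule written after the values had been seen. The leukocyte list's median of -0.14 has a bootstrap 95% interval from -0.83 to 0.23, above both lists' medians. Of its 11 members without a level in the A-CEBP sample, 0 were well above background in the GFP sample. Among inflammatory genes without such a level this was 9 of 17, which restates the pattern itself. A partial contribution of leukocytes, of a size that the wide interval cannot settle, stays open. Lower NF-kB-driven transcription may contribute: 27 NF-kB feedback genes outside the fixed lists had a median of -0.53 (percentile 0.00). That set was chosen after the inflammatory difference had been seen. Its lower median could go with lower inflammatory expression of any cause, so it cannot single out NF-kB. With 1 array per group, an effect of A-CEBP cannot be told apart from any other difference between the lines or cultures.

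Genes of hypoxia, glycolysis and cartilage were higher in the A-CEBP sample. A bias that depends on intensity is argued against, because the hypoxia median stayed at 0.65 after cyclic loess. Lower expression of the respiratory chain is argued against by a median of 0.0841 over 52 of its nuclear genes. A wider HIF-linked programme may be involved: 23 HIF targets outside the fixed lists had a median of 0.41, above all 10000 random lists. That set was chosen after the hypoxia list had been seen to be higher, and it cannot single out HIF among causes of that pattern. Oxygen supply or cell density that differed between the dishes was not tested and stays open.

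Differences spread over the genome were checked for shifts shared by neighbouring genes, as a copy number difference between the 2 stable lines would give. The largest absolute median over 30 neighbouring genes, relative to all genes, was 0.23, on chromosome 5, under the bound of 0.4 set beforehand. It lay just above the 95th percentile of 0.2312 under 1000 shuffles of gene order. Gains or losses of under 30 genes, or larger ones that shift expression by less than the bound of 0.4, are not excluded.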

How the results depend on the processing

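Spike-in scaling was chosen after seeing the data; the other alternatives were planned. All 410 genes kept their sign under every setting of scaling, background, filter and gene value in which they were measured. Sizes moved more. Over the named genes and settings, 1155 log2 differences stayed within 0.12, the replicate-spot SD, of the main value and 240 did not. For lower bounds these numbers were 48 and 16. The main counts were 410 genes at least 2-fold apart, 173 higher and 237 lower. With normexp background 272 passed (98 higher), and with quantile normalization added 262 (91 higher). Without a detection filter 1487 passed (601 higher, 886 lower), because dim genes entered, and with the stricter filter 114 were higher. Spike-in scaling gave 351 higher. The authors' deposited values gave 137 higher and 259 lower, as the median of all genes moved from 0.0445 to -0.0061. Genes just past the rule upward, such as Papss2, Fmod, Cnmd, Sfrp4 and Id2, then fell under it. By construction, the size rule set the counts: 1179 at 1.5-fold (649 higher, 530 lower), 134 at 3-fold (27 and 107) and 81 at 4-fold (11 and 70). Genes seen in the GFP sample only numbered 171, or 544 by the scanner's less strict flag, 97 with a bound of at least 2-fold and 51 of at least 4-fold. Those in the A-CEBP sample only numbered 674, or 911 by that flag, and 63 and 11 by these bounds. The cartilage median of 0.59 was 0.43 with normexp, 0.40 (0.3950) with normexp and quantile, 0.43 (0.4281) with the mean of a gene's probes and 0.81 with spike-in scaling. The hypertrophic median of 0.53 was 0.40 (0.3953) with normexp and quantile and 0.76 with spike-in scaling. The inflammatory median of -1.28 was -1.06 with spike-in scaling. Signs reversed with spike-in scaling for the C/EBP family (0.0657), S and G2/M phase (0.16), proteases (0.1732) and stress (0.1728) lists, with no scaling for proteases (0.0037) and stress (0.0034), and with no detection filter for muscle (-0.0858). The hedgehog median of 0.45 was 0.20 with no filter and 0.33 with normexp and quantile, that of muscle 0.34 with normexp and 0.40 with quantile added, and that of proteases -0.18 with the stricter filter. Medians of lists within the central 95% of random lists also crossed 0: the leukocyte list with spike-in scaling (0.08) and no filter (0.0186), the adipocyte list under 5 settings (lowest -0.0206), ATF4 with quantile normalization (-0.0120) and cell cycle inhibitors with no filter (-0.0040). List percentiles left the central 95% in 6 cases and entered it in 3: the range was 13.1 to 99.5 for cell cycle inhibitors, 82.6 to 99.4 for the endothelial, 0.44 to 58.7 for the leukocyte, 61.2 to 100 for the muscle and 0.04 to 7.87 for the stress list. Apart from the scaling shift, the normexp offset and the added dim genes, the cause was not tested. No paired analysis was possible because each group had 1 array, which also ruled out leaving out replicates. Signal over background limits dim genes, whose replicate-spot SD was 0.18 against 0.06 for bright ones.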

Other observations

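The added gene sets, and the genes named here, were chosen after the main differences had been seen. Genes that feed back on NF-kB, the transcription factor of inflammatory signalling, were lower in the A-CEBP sample, with 9 of 27 at least 2-fold lower and none higher by that size. The receptor gene Tlr2 differed by -2.36, Nfkbiz by -1.93, Map3k8 by -1.87 and the inhibitor gene Nfkbia by -1.47, while Rela, which encodes a subunit of the factor, differed by -0.10. Outside this set, in the fixed inflammatory list, Nos2, which encodes inducible nitric oxide synthase, differed by -4.13 and the cytokine gene Il6 by -4.11.

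In the added set of HIF targets, 5 of 23 genes were at least 2-fold higher in the A-CEBP sample and none lower by that size. The lactate transporter gene Slc16a3 differed by 1.25, Tmem45a by 1.14, the adenylate kinase gene Ak4 by 1.03 and Fam162a by 1.01. Ak4 and Fam162a fell under the 2-fold rule with the authors' deposited values. Errfi1 went the other way, at -0.71. Among 52 nuclear genes of the respiratory chain none was 2-fold apart. Myogenic regulators Myod1, Myog and Myf5 were not well above background in either sample, and Myf6 was so in the GFP sample only, at least 2.92-fold lower in the A-CEBP sample, where Mb and Tnni2 were higher in the A-CEBP sample.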
